A study of Mus musculus with 6 samples.

How the data were processed

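ATAC-seq libraries of mouse liver, 3 fasted and 3 refed, were grouped by the treatment and titles in the labels; the groups share no replicate number, so no pairing was used. Per the labels' protocols, nuclei were isolated from 50 to 100 mg of fresh tissue and about 50000 nuclei entered each transposase reaction. Per the submitters' processing notes, the tools were FastQC, cutadapt, Bowtie2, SAMtools, MACS2, DESeq2 and HOMER with the mm9 genome; their versions and settings, and whether reads were shifted for the transposase offset, are not given in the sources used here. Per the file headers, reads were quantified over 1 merged set of peaks, duplicates were removed, unique reads were kept, and peaks were annotated with HOMER.

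The authors' table of individual replicates holds RPKM values, reads scaled to the length of the peak in kilobases and to the library's reads in the listed peaks, and the deposited log2 columns are the log2 of these. A peak with no read was set by the authors to the value of 0.9 reads, which was worked out from the values. The scale divides by reads in peaks, so it removes any difference between libraries in the total share of reads in peaks. Whole reads were recovered from the RPKM steps at a tolerance of 0.01 reads. The recovered reads were whole, or at the 0.9 reads of an empty peak, for 100% of peaks in each library, and equalled the read counts in the authors' deposited edgeR table at all 3314 peaks listed there. The same table gives the authors' p-value, FDR and log2 fold change for peaks under an FDR of 0.05. The authors' deposited ratio of mean RPKM and an unadjusted p-value per peak were used only to describe the files: 8885 peaks have such a p under 0.05. The authors' pooled RPKM of each group equalled the summed reads and were not used further. The notes name DESeq2 while the deposited table names edgeR.

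A spreadsheet had turned the symbols of 91 peaks into dates; all 91 were restored through Entrez gene IDs in a RefSeq gene table of another assembly, used for names only. Gene symbols follow the file's nearest gene start, and the transcript named in the annotation is given where it is a different gene. Coordinates are 1-based mm9 positions as in the files. Motifs were not analysed here, since no mm9 sequence was used.

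The main test was fitted to the log2 RPKM of all 74076 peaks with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), refed minus fasted, without a filter, a pseudocount or a covariate. P-values were adjusted by Benjamini-Hochberg over all peaks and called at 0.05. Changes are on the log2 RPKM scale with limma's standard error; means and SDs are of RPKM over 3 libraries. At low peaks the 0.9 reads set for empty peaks makes the fold change smaller than it would otherwise be. On the recovered reads, edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, which kept 61067 peaks) and DESeq2 1.42.0 were run as alternatives; DESeq2 gave no adjusted p for 18693 peaks.

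Gene lists numbered 25, with 388 symbols, and covered fasting and feeding pathways and markers of cell types. They were tested with camera (limma) at a preset correlation of 0.01 over lists of at least 5 peaks, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, which tests a list without comparing it to other peaks. Camera compares a list with all other peaks, so its direction can differ from the sign of the list's mean or median. For bile acid genes, endothelial cell markers and autophagy it pointed down with a mean above 0 (for autophagy the median was below 0). For pericentral markers it pointed down with a mean below 0 and a median above 0. Promoter peaks were those in the file's promoter class, and Fisher's exact test was two-sided. Fisher's test treats peaks of 1 gene as independent.

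The tests, the gene lists, the rule for named peaks and the alternatives were fixed before the data were examined, except where said otherwise. The rule took the 10 largest changes in each direction among called peaks whose groups did not overlap, 1 per gene and skipping predicted genes. It also took the 3 genes with the smallest p in each called list, in the first 4 metabolic lists and in the circadian list, and 10 index genes at their strongest peak. In total 53 peaks were named by it. Genes of a list that are given only by name are members with a called peak. Some genes taken by the rule or in the lists are not reported here; they remain in every count.

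Reads were simulated for the same peaks and depths, with 200 changed peaks drawn from those with a mean of at least 10 reads. On these, limma recovered 1.49%, 26.9% and 65.2% of 1.5-, 2- and 3-fold changes and made 0 false calls among 73876 unchanged peaks. The same simulated reads gave edgeR 10.4%, 52.2% and 84.8% with 5 false calls, and DESeq2 4.48%, 32.8% and 66.7% with 0. The simulated noise was independent between peaks, and libraries of a group differed only in depth. Only 200 of the 74076 peaks were changed, and recovery at a fixed adjusted p depends on how many peaks change. These rates may therefore not hold for the real libraries or for weaker peaks. Alternatives covered scaling, filters, prior variance, thresholds, count tests, gene assignment, promoter windows and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.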

Results

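Open chromatin was profiled in mouse liver by ATAC-seq, in which a transposase cuts accessible DNA and tags it for sequencing. There were 3 libraries from fasted and 3 from refed male C57BL/6J mice, an inbred laboratory strain, at 8 weeks of age. The fasted group had no food for 12 h from 10 pm. The refed group was fasted for 12 h from 10 am and then ate a diet of 69% sucrose and 10% fat for 12 h, and both groups were killed at 10 am. The comparison asks where liver chromatin is more or less open after 12 h on a sucrose-rich diet than at the end of a 12 h fast. The groups also differed in the hours of the fast, and no group was refed on another diet. Effects of eating, of this diet and of the time of feeding therefore cannot be told apart. The labels do not say that each library came from its own animal, so the p-values measure the spread between these libraries.

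The table held 74076 peaks on 21 chromosomes of the mm9 genome, with a median width of 435 bp. Reads within these peaks numbered 4850613, 3205634 and 4088425 in fasted replicates 1, 3 and 4, and 4176671, 3238712 and 4679316 in refed replicates 5, 7 and 8. The median peak held between 19 and 33 reads per library, so values at an average peak rest on few reads. Across peaks, log2 RPKM correlated at 0.929 to 0.955 among fasted libraries, 0.937 to 0.958 among refed libraries and 0.910 to 0.941 between groups (Pearson's r, across peaks, which are not independent replicates). The first principal component held 33.5% of the variance and parted the groups, with fasted scores from -96.3 to -23.4 and refed scores from 39.1 to 94.9. The second component held 28.5%, and its lowest scores were those of fasted replicate 3 and refed replicate 7, the libraries with the fewest reads.

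**Figure D1:**
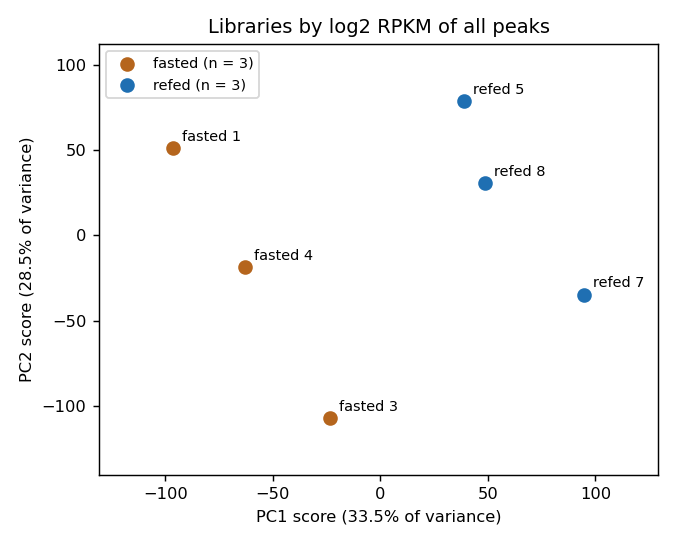
Scores of the 6 libraries on the first and second principal components of the log2 RPKM values of all 74076 peaks; each point is 1 library, coloured by group. The 3 fasted libraries lie at -23.4 or below on the first component and the 3 refed libraries at 39.1 or above.

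Refed liver was more open than fasted liver around Fasn, Scd1, Thrsp, Pklr and Gpi1, genes of fatty acid synthesis and sugar breakdown. It was less open around Pck1, Tat, Tdo2, Hpd and Cyp4a14, genes of glucose production, amino acid breakdown and fatty acid hydroxylation. The strongest gain was 4.03 on the log2 scale and lay just beyond the 3′ end of Fasn, which encodes fatty acid synthase. The strongest loss was -3.98 ± 0.59 (SE, limma adjusted p = 0.00856) and lay beyond the 3′ end of Cyp4a14, a cytochrome P450 gene. That peak held only 2, 3 and 10 reads in refed replicates 5, 7 and 8. In all, 594 peaks were higher and 316 lower in refed liver (limma, adjusted p under 0.05), 1.23% of the peaks tested.

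The called peaks had a median log2 change of 1.35 when higher and -1.12 when lower, and 466 higher and 205 lower peaks changed by at least 2-fold. At each of the 910 called peaks the 3 refed values all lay on one side of the 3 fasted values, against 19% of all peaks and 10% by chance; peaks that pass such a threshold nearly have to, so this is no separate evidence. The same test gave 10778 peaks at an unadjusted p under 0.05. On the recovered read counts, edgeR called 1573 higher and 876 lower peaks and DESeq2 called 578 and 341. The authors' deposited table of edgeR calls lists 3314 peaks, 2083 higher and 1231 lower in refed liver. All 3314 had the same direction in the limma fit, which uses the same libraries, and 882 of them, 26.6%, passed its threshold. Without an intensity trend in the prior variance limma called 0 peaks, with 10454 at an unadjusted p under 0.05, and after quantile normalization it called 71 higher and 23 lower peaks against the 594 and 316. With median centring it called 886 and 607, and with array weights 6524 and 3162. The counts of higher and lower peaks were 970 and 205 without fasted replicate 1, 181 and 48 without fasted replicate 4, 233 and 206 without refed replicate 5, 174 and 148 without refed replicate 7, and 77 and 73 without refed replicate 8.

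The peak beyond Fasn, at chromosome 11 from 120664989 to 120666695, is intergenic and was assigned by the file to Dus1l, whose start is the nearest. Its accessibility was 5.68 ± 1.57 RPKM in fasted and 94.8 ± 37.9 RPKM in refed liver (mean ± SD, n = 3 each), a log2 change of 4.03 ± 0.28 (SE, limma adjusted p = 6.39e-05). A neighbouring peak from 120666864 to 120667259, annotated as the transcription end of Fasn, rose by 2.40 ± 0.23 (adjusted p = 0.000617). The peak in the 5′ UTR of Fasn, in exon 1 of 43, had 70.5 ± 8.04 RPKM in fasted and 84.5 ± 12.2 RPKM in refed liver and did not pass (adjusted p = 0.278). At Pck1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, the peak in the 3′ UTR (chromosome 2, 172984123 to 172984632, exon 10 of 10) had 62.8 ± 6.27 RPKM in fasted and 7.76 ± 3.34 RPKM in refed liver. That loss was -3.10 ± 0.27 on the log2 scale (adjusted p = 0.000489), whereas the Pck1 promoter peak differed by -0.43 ± 0.10 and did not pass (adjusted p = 0.0579), although edgeR called it (adjusted p = 0.0348).

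**Figure D2:**
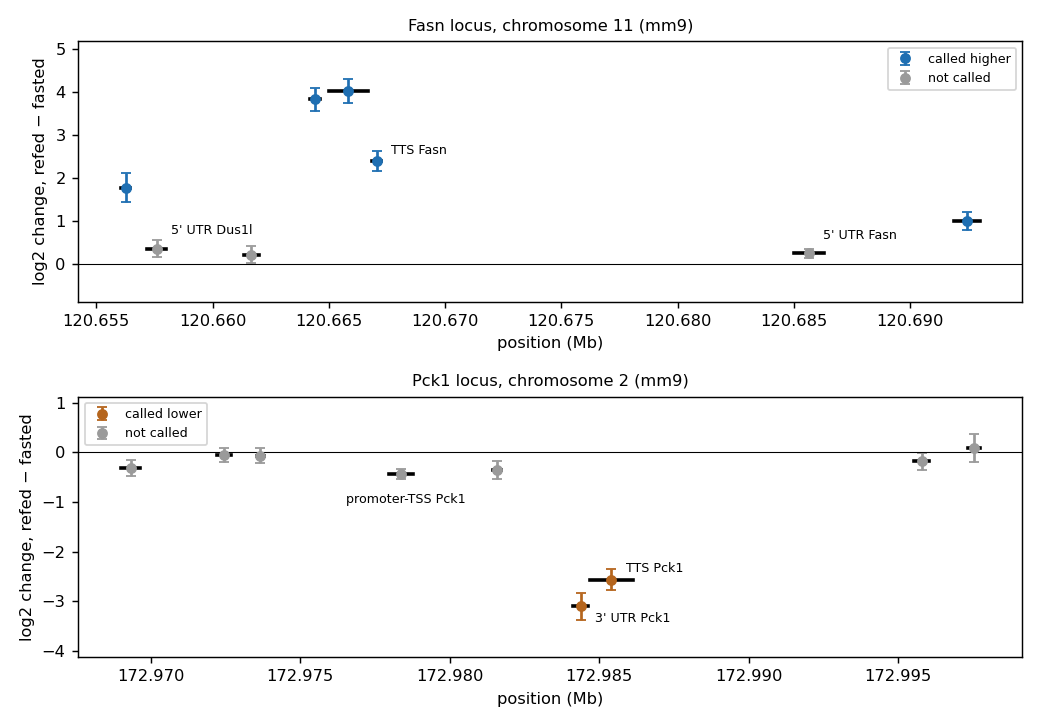
Log2 change in accessibility (refed minus fasted, with its SE) against position on mm9 for every peak around Fasn on chromosome 11 and Pck1 on chromosome 2; black bars span the peaks and colours mark the calls. The transcription end peak of Fasn and the 2 intergenic peaks next to it changed by 2.40 to 4.03. Further on, an intergenic peak (0.23) and a Dus1l 5′ UTR peak (0.37) were not called, while a Dus1l exon peak was called higher (1.78). Upstream of the Fasn start, a peak in an intron of Ccdc57 was called higher (1.00). Peaks at the 3′ end of Pck1 changed by -3.10 and -2.57, while the Fasn 5′ UTR and Pck1 promoter peaks were not called by limma.

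Other peaks with the largest gains lay at the 3′ end of Scd1, the stearoyl-CoA desaturase gene (chromosome 19, 44468263 to 44468978), with a log2 change of 3.33 ± 0.33, and at the 3′ end of Thrsp (chromosome 7, 104559735 to 104561297), with 2.93 ± 0.27. A peak in the 3′ UTR of the fatty acid elongase gene Elovl6 (chromosome 3, 129340027 to 129340240), assigned to Egf by nearest start, rose from 3.68 ± 2.45 to 24.5 ± 7.54 RPKM. Intronic peaks in Uba2 (intron 6 of 16) and Hormad2 (intron 1 of 10) rose by 3.57 and 3.20, and an intronic peak in Uvrag assigned to Wnt11 rose by 2.82. Intergenic peaks assigned to Mir1983, Ube2e3 and Efna5 rose by 3.19, 3.16 and 2.93; those of Ube2e3 and Efna5 lie 281268 and 129753 bp from the assigned start. These peaks were weak in fasted liver, with at most 12 reads per library at the peaks of the Elovl6 3′ UTR, Uba2, Hormad2, Mir1983, Ube2e3, Efna5 and Wnt11.

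Among losses, an intronic peak of Cyp4a32 (chromosome 4, 115278970 to 115280738, intron 4 of 12) had a log2 change of -3.37 ± 0.47; it lies on the same chromosome as the Cyp4a14 peaks. Members of the Cyp4a family are close copies. Only unique reads were kept, so reads that match several copies may be missing from these peaks. A peak at the 3′ end of Slc7a2, an amino acid transporter gene, assigned to Pdgfrl, changed by -3.32 ± 0.59. The peak assigned to Tdo2, the tryptophan dioxygenase gene, lies at the 3′ end of its neighbour Ctso (chromosome 3, 81759972 to 81761598) and went from 43.6 ± 10.1 to 6.22 ± 1.25 RPKM. The peak assigned to Hpd, a tyrosine breakdown gene, changed by -2.20 ± 0.33. Peaks assigned to Tusc5, Cox6c, Cobll1 and Antxr2 changed by -2.72, -2.54, -2.52 and -2.38. The Cox6c peak lies in Vps13b (exon 46 of 62), 61800 bp from the start of Cox6c. These losses rest on few reads in refed replicates 5, 7 and 8. Reads there were 2, 6 and 15 for Tusc5, 3, 0 and 6 for Cox6c, 5, 2 and 3 for Cobll1, and 4, 2 and 5 for Antxr2. The Slc7a2 peak held 2, 6 and 20 reads in these libraries. The Cyp4a14 peaks held 2, 3 and 10 beyond its 3′ end and 2, 1 and 3 at its 3′ end. Of the 37 named peaks that were called, 37 lost the call without an intensity trend and 26 with quantile normalization. It was lost by 6, 4 and 11 of them without fasted replicate 1, 3 and 4, and by 5, 11 and 14 without refed replicate 5, 7 and 8; the peak of Cox6c lost it in 5 of these 6 fits, those of Tusc5, Antxr2 and Ube2e3 in 4 each, that of the Elovl6 3′ UTR in 3, without refed replicate 5, 7 or 8 (adjusted p = 0.0745, 0.0901 and 0.0703), those of Cobll1, Hormad2 and Wnt11 in 2 each and those of Slc7a2, Uba2, Mir1983 and Efna5 in 1 each.

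**Figure D3:**
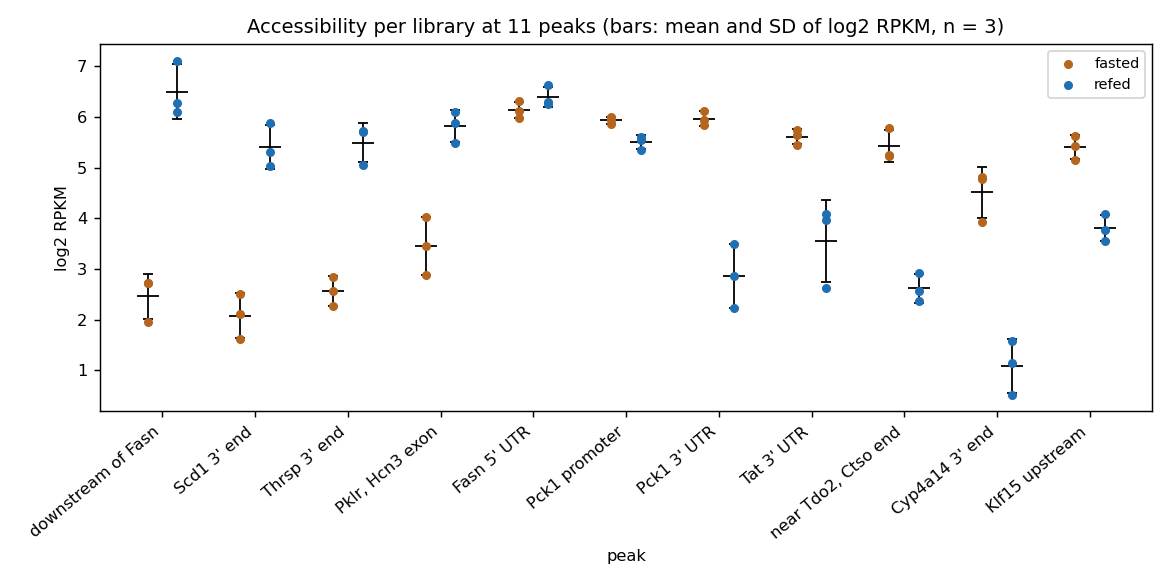
Log2 RPKM in each library (points; fasted brown, refed blue) at 11 named peaks, with bars for the mean and SD of the log2 values (n = 3 per group). The groups are apart at the 3′ ends of Scd1, Thrsp, Pck1, Tat and Cyp4a14, and lie close together at the Fasn 5′ UTR, where the adjusted p was 0.278.

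Genes of fatty acid synthesis had the smallest p of 25 preset gene lists in camera with its preset correlation, though not with an estimated one or in fry. Peaks assigned to targets of the lipogenic factors SREBP-1c and ChREBP were higher in refed liver as a group (camera adjusted p = 1.12e-06; adjusted p = 0.417 with an estimated correlation). Of its 22 genes, 12 had a higher peak, 0 had a lower one by limma and 10 had none that passed. The 12 were Acaca, Acacb, Acly, Elovl5, Elovl6, Fasn, Gpam, Me1, Mid1ip1, Pnpla3, Scd1 and Thrsp; Fasn counts through a peak in an intron of Ccdc57, since the peaks beyond its 3′ end are assigned to Dus1l. The 152 peaks of this list held 21 higher calls over all peaks tested; adjusted over the list alone, 35 peaks were higher and 5 lower. At an unadjusted p under 0.05 there were 56, while edgeR called 29 higher and 2 lower and DESeq2 called 17 in all. The Elovl6 promoter peak rose from 36.4 ± 4.40 to 61.0 ± 4.38 RPKM (log2 change 0.75 ± 0.12), and a peak 8711 bp upstream of Scd1 rose from 14.6 ± 1.06 to 51.5 ± 9.87 RPKM. For this list fry gave an adjusted p of 0.151, and over its alternatives the adjusted p ran from 9.1e-09 to 0.417.

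Genes of glycolysis, fructose breakdown and the pentose phosphate pathway were also higher as a group (camera adjusted p = 8.44e-05; adjusted p = 0.0812 with an estimated correlation; fry adjusted p = 0.00104; 2.77e-05 to 0.31 over its alternatives, the highest with only peaks within 2 kb of a gene start). Of 21 genes with a peak, 7 had a higher peak, 2 had a lower one and 13 had none that passed, with the glycogen-targeting subunit gene Ppp1r3b in both of the first groups. Its 110 peaks held 10 higher and 2 lower calls; adjusted over the list alone, 25 were higher and 4 lower. A peak 11365 bp downstream of the start of Pklr, the liver pyruvate kinase gene, lies in the last exon of its neighbour Hcn3 (exon 8 of 8; chromosome 3, 88950943 to 88952878). It rose from 11.5 ± 4.49 to 57.3 ± 12.1 RPKM, a log2 change of 2.37 ± 0.26 (limma adjusted p = 0.00144). A peak in intron 4 of 17 of Gpi1, the glucose-6-phosphate isomerase gene, rose by 1.27 ± 0.17. The glycogen synthase gene Gys2 had a lower peak.

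Some genes that serve glucose production, amino acid breakdown, fat burning and glucocorticoid responses had lower peaks in refed liver, and camera called these lists lower, as it did lymphocyte markers (adjusted p = 0.042), of which no single peak passed. With an estimated correlation none of these 5 calls held (adjusted p = 0.464 for gluconeogenesis, 0.244 for PPARA targets and 0.324 for each of the others). Tat belongs to 3 of these lists. In the amino acid catabolism and urea cycle list, 4 of 20 genes had a lower peak (Hpd, Sds, Tat and Tdo2) and 0 a higher one (limma), with 36 of its 137 peaks at an unadjusted p under 0.05, 1 higher peak by edgeR and 9 calls in all by DESeq2. Its camera adjusted p was 4.3e-05, with adjusted p = 0.324 with an estimated correlation; adjusted over the list alone, 17 peaks were lower and 2 higher. The 3′ UTR of Tat, the tyrosine aminotransferase gene (chromosome 8, 112522260 to 112523387, exon 12 of 12), fell by 2.06 ± 0.31 on the log2 scale, and the 3′ end of Sds, the serine dehydratase gene, fell by 2.04 ± 0.30. In the gluconeogenesis list, 9 of 21 genes had a lower peak (Creb3l3, Crtc2, Foxo3, Klf15, Pck1, Pfkfb3, Ppargc1a, Sds and Tat), 2 a higher one (Igfbp1 and Sik1) and 10 had none that passed. Pfkfb3 is known for promoting glycolysis. A peak 1198 bp upstream of Klf15 fell by 1.60 ± 0.19. This list had a camera adjusted p of 0.032 and adjusted p = 0.464 with an estimated correlation; adjusted over the list alone, 22 peaks were lower and 10 higher. Its camera call was lost without fasted replicate 1, fasted replicate 3 or refed replicate 5 (adjusted p = 0.057, 0.0649 and 0.0654), with quantile normalization (0.257), without an intensity trend (0.0696) and among peaks above the first quartile of the mean (0.076). Over the alternatives, the adjusted p ran from 6.63e-06 to 0.532 for the amino acid list and from 0.00424 to 0.625 for gluconeogenesis, both highest with the strongest peak per gene.

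Targets of PPARA, the receptor that drives fatty acid oxidation and ketone production, had lower peaks at 5 of 25 genes (Acadm, Angptl4, Cyp4a14, Fabp1 and Pdk4), and Fabp1 also had a higher one. The camera adjusted p was 8.44e-05, with adjusted p = 0.244 with an estimated correlation; adjusted over the list alone, 21 peaks were lower and 10 higher. Peaks 2788 bp upstream of Acadm and 13479 bp upstream of Pdk4 fell by 1.34 ± 0.24 and 1.30 ± 0.26, the latter losing its call in 4 of the 6 fits with 1 library left out, while the Pdk4 promoter stood at 77.4 ± 5.11 RPKM in fasted and 77.5 ± 7.12 RPKM in refed liver (adjusted p = 0.999). Glucocorticoid receptor targets had lower peaks at 7 of 16 genes (Errfi1, Fkbp5, Gadd45b, Klf9, Mt1, Mt2 and Tat) and higher ones at Gadd45b and Lpin1. Their camera adjusted p was 0.00073, with adjusted p = 0.324 with an estimated correlation; adjusted over the list alone, 19 peaks were lower and 6 higher. The Klf9 peak, 78231 bp upstream of the gene start, fell by 1.68 ± 0.25 and the Errfi1 peak by 0.66 ± 0.10. These lost their calls without fasted replicate 4 (0.0539) and refed replicate 8 (0.0503), as the Acadm peak did without fasted replicate 4 (0.0738). In the cytochrome P450 and xenobiotic metabolism list, Alas1 and Cyp2b10 had lower peaks, which fell by 0.91 ± 0.19 and 1.52 ± 0.34 but lost their calls in each of the 6 fits with 1 library left out. The Por peak differed by -1.02 ± 0.24 (adjusted p = 0.0616; edgeR 0.00266; 0.0389 with median centring). That list had a camera adjusted p of 0.0096 and adjusted p = 0.417 with an estimated correlation; adjusted over the list alone, 3 peaks were lower and 1 higher, and its camera call was lost without fasted replicate 1 (adjusted p = 0.0744). With only peaks within 2 kb of a gene start, PPARA targets were the only one of the 5 lower metabolic lists to pass (adjusted p = 0.00027), and with the strongest peak per gene none did (0.053 for PPARA, 0.315 for glucocorticoid and 0.684 for P450 genes). None of the 5 passed in fry (adjusted p = 0.0599 for PPARA, 0.151 for amino acid, 0.151 for glucocorticoid, 0.192 for P450 and 0.223 for gluconeogenesis genes). Over the alternatives, the adjusted p ran from 3.66e-05 to 0.244 for PPARA, from 0.000226 to 0.735 for glucocorticoid and from 0.000406 to 0.684 for P450 genes.

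Markers of lymphocytes, a cell type other than hepatocytes that liver tissue holds, moved with these lists. Their 12 peaks, at 6 of 15 genes, had a mean log2 change of -0.38 (camera adjusted p = 0.042; adjusted p = 0.324 with an estimated correlation; fry adjusted p = 0.00475). No single peak passed: limma, edgeR and DESeq2 called 0 of them, with 2 at an unadjusted p under 0.05, and adjusted over the list alone 0 passed. Cd3d, a T cell receptor chain gene, had 17.1 ± 3.76 RPKM in fasted and 7.27 ± 2.85 RPKM in refed liver at its 3′ UTR (adjusted p = 0.131). Lck had 11.9 ± 3.64 and 4.86 ± 0.167 RPKM (adjusted p = 0.166) and Ptprc 14.7 ± 2.74 and 9.87 ± 1.53 RPKM (adjusted p = 0.436). The camera call for lymphocyte markers was lost without fasted replicate 1, 3 or 4, refed replicate 7 or refed replicate 8 (adjusted p = 0.106, 0.0627, 0.0565, 0.0786 and 0.0938). It did not pass with the strongest peak per gene (adjusted p = 0.0921) or among peaks above the first quartile of the mean either (0.468, the highest of its alternatives; the lowest was 0.00475).

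The remaining lists were not called by camera. Adjusted p was 0.127 for cholesterol synthesis, where Dhcr7, Sc5d and Sqle were among the genes with a higher peak, 0.174 for proliferation, 0.605 for insulin and growth hormone signalling, 0.626 for the unfolded protein response, 0.929 for bile acid genes, 0.989 for autophagy and 0.567 for housekeeping promoters. For cell markers it was 0.626 for hepatocytes, 0.064 for periportal and 0.989 for pericentral hepatocytes, 0.72 for Kupffer cells and macrophages, 0.982 for endothelial cells, 0.522 for stellate cells, 0.662 for cholangiocytes, 0.818 for neutrophils and 0.989 for erythroid cells. The circadian list had an adjusted p of 0.608, with 6 peaks higher and 6 lower when adjusted over the list alone. Its peak at the promoter of Npas2, a clock transcription factor gene, rose from 18.5 ± 3.73 to 37.3 ± 3.90 RPKM, a log2 change of 1.02 ± 0.19 (limma adjusted p = 0.0213), and lost its call without refed replicate 7 or 8 (0.0852 and 0.0916). Peaks of Per2 and Nr1d1 differed by 0.72 ± 0.16 and 0.63 ± 0.15 and did not pass (adjusted p = 0.0538 and 0.0572). Per2 passed with median centring and without fasted replicate 1 (0.0398 and 0.0225), and Nr1d1 without fasted replicate 3 (0.0314).

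**Figure D4:**
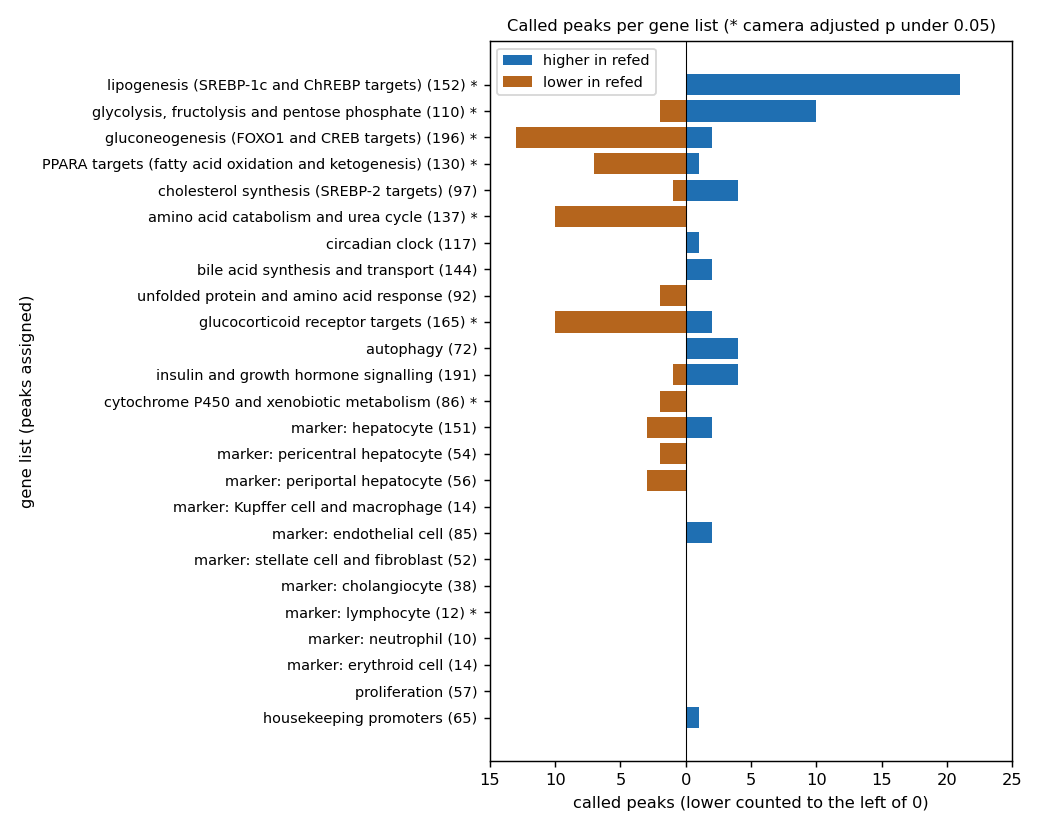
Number of called peaks in each of the 25 gene lists, higher in refed liver to the right of 0 and lower to the left, with the number of assigned peaks in brackets and an asterisk where camera's adjusted p was under 0.05. The lipogenesis list holds 21 higher and 0 lower calls by limma, and the amino acid catabolism list 0 higher and 10 lower, where edgeR gave 1 higher.

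Several genes known for their response to feeding had no called change at their strongest peak. The promoter of Srebf1, the gene of the lipogenic factor SREBP-1c, stood at 40.9 ± 3.05 RPKM in fasted and 43.0 ± 1.37 RPKM in refed liver (limma adjusted p = 0.847), that of Irs2 at 76.9 ± 2.35 and 80.4 ± 7.15 RPKM (adjusted p = 0.829) and that of Cpt1a at 58.5 ± 6.52 and 55.3 ± 6.48 RPKM (adjusted p = 0.835). The strongest peaks of G6pc and Igfbp1 differed by 0.29 ± 0.14 and 0.24 ± 0.11 (adjusted p = 0.351 and 0.347), although Igfbp1 had a called peak elsewhere. The Pklr promoter differed by 0.62 ± 0.17 (adjusted p = 0.0904; edgeR 0.039) and passed without fasted replicate 3 (0.0377).

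Changed peaks lay at promoters less often than other peaks. Of the 594 higher peaks 27 were at a promoter, and of the 316 lower peaks 23, against 9220 of all 74076. The odds ratio was 0.333 (95% interval 0.217 to 0.490, two-sided Fisher's exact test, adjusted p = 1.24e-09 over 16 tests) for higher and 0.551 (0.344 to 0.844, adjusted p = 0.0145) for lower peaks. Among lower peaks, transcription ends were over-represented (17 of them, against 1080 of all peaks; odds ratio 3.89, adjusted p = 4.2e-05), as were 3′ UTRs (8, against 608; odds ratio 3.17, adjusted p = 0.0158). Higher peaks had odds ratios of 1.88 for transcription ends (adjusted p = 0.052) and 1.25 for introns (adjusted p = 0.0233). Without refed replicate 8 the odds ratio for higher peaks was 0.488 and did not pass. For lower peaks it did not pass without fasted replicate 1, fasted replicate 4, refed replicate 5, refed replicate 7 or refed replicate 8 (0.933, 0.469, 0.673, 0.620 and 0.630), and with a window of 5 kb around the gene start it was 1.14 (Fisher's exact p = 0.285).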

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

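All alternatives were planned, except the promoter share of reads as a covariate, the gene named by the annotation, and the alternatives for the group separation, which were chosen after seeing the data. Pseudocounts were not varied, since the deposited values are on a log scale. The count of higher and lower peaks (594 and 316) moved with most of the settings of the test. It was 0 and 0 without an intensity trend, where the smallest adjusted p in limma was 0.0678 and 10454 peaks had an unadjusted p under 0.05, and edgeR and DESeq2 gave the counts below. It was 71 and 23 with quantile normalization, of which 82 were among the reported calls, and 607 lower peaks (886 higher) with median centring, where 879 of the reported calls remained. Array weights gave 6524 and 3162, with a weight of 4.60 on fasted replicate 4 against 0.479 to 1.75 on the others. An adjusted p of 0.10 gave 1483 and 747. At an adjusted p of 0.05, a further limit of 1 on the log2 scale gave 466 higher and 205 lower peaks. With edgeR the counts were 1573 and 876, or 1579 and 915 without its filter; DESeq2 gave 578 and 341. The cause of these differences was not tested, beyond what thresholds and weights do by construction.

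Leaving out 1 library gave 77 to 970 higher and 48 to 211 lower peaks, with fewer libraries in each fit. The lowest share of reported calls kept was 145 of 910, without refed replicate 8, and the highest 675, without fasted replicate 1. The other settings (filters, robust moderation, autosomes, the covariate) stayed within 1.5 times of both counts. All 3314 of the authors' peaks kept their direction under median centring, quantile normalization and each library left out (3314 to 3314). They were selected as calls on the same libraries, so this is no separate evidence.

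The lists called higher and lower (2 and 6) were 0 and 0 with an estimated correlation in camera, where the lowest adjusted p was 0.0812, and 1 and 1 with fry, the lower one being lymphocyte markers. Lists called lower were 1 with only peaks within 2 kb of a gene start and 0 with the strongest peak per gene, which have fewer peaks. Leaving out 1 library gave 2 to 3 and 3 to 6, the 3 without fasted replicate 1. The lymphocyte list was not called with the gene named by the annotation (0.228). The promoter odds ratio ran from 0.262 to 0.488 for higher and 0.461 to 0.933 for lower peaks when 1 library was left out, and the lower one was 1.14 with a 5 kb window. The first component held 38.6% of the variance in log2 CPM, and 36.5% to 43.2% with 1 library left out.

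Of the 37 called named peaks, 11 lost the call only without an intensity trend. Of all named peaks, the Pdk4 promoter (0.00) turned to -0.036 with median centring and to -0.071 and -0.054 without refed replicate 7 and fasted replicate 1, within a range of -0.071 to 0.057 over libraries left out. The Cpt1a promoter ran from -0.17 (without fasted replicate 1) to 0.014 (without refed replicate 5); none of these was called. On reads simulated at these depths, recovery of 2-fold changes at peaks with a mean of at least 10 reads was 26.9% with limma and 52.2% with edgeR. Other depths, other numbers of changed peaks and changes at weaker peaks were not simulated. No change can be seen at 3733 peaks, which held 0 reads in all 6 libraries.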

Other observations

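The tests of 1 peak per gene, of promoter against 3′ end sizes, of all other peaks of a gene and of called peaks that lie over 2 kb apart, and the choice of the patterns, came after seeing the data; the raw counts of the 3 patterns were known before any of their tests. Beyond the named genes, lower peaks lay at the 3′ ends of Alb (log2 change -1.64), the serum albumin gene, Cyp2e1 (-1.85), Mat1a (-1.27) and Slc25a47 (-0.79), all past the limma threshold. Higher peaks lay at the 3′ ends of Pgd (1.29 and 1.05), a pentose phosphate gene. These were chosen after their values were seen, and the file assigns the peaks of Alb, Mat1a and Pgd to the neighbours Afp, Sftpa1 and Apitd1. LINE L1 elements held 1.31% ± 0.0186 of reads in peaks in fasted and 1.47% ± 0.0308 in refed libraries (mean ± SD, n = 3), an exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. Of 6604 peaks with under 10 reads in total, 59.1% lie in L1 elements, against 11.1% of all peaks.

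Changed peaks lay at gene 3′ ends (transcription ends and 3′ UTRs together, a choice made after seeing the data) more often than other peaks, 49 of 910 against 2.28% of all. The odds ratio was 2.15 (95% interval 1.57 to 2.89) within deciles of mean signal, which argues against signal level as the whole cause. With 1 peak per gene it was 1.54 (1.06 to 2.16, the median of 100 random draws of the other peaks). Genes with a call kept their called peak with the smallest p, and other genes kept a random peak. The lower bound was above 1 in 99 draws, which vary only the random peaks. The test first used 1 draw, which gave 1.49 (1.03 to 2.10). The draws and the rule for reading them were added after that value was seen. Choosing called peaks by their p and the others at random could itself move the odds ratio. This test therefore cannot settle whether several peaks of a few genes are the whole cause. It also changes the comparison peaks to 1 per gene and is not matched on signal. The difference from the odds ratio over all peaks (2.48) therefore has no single cause tested here. In 32 genes with a promoter peak, the median promoter change in the direction of the 3′ end was 0.076 against 1.35 at the 3′ end. The ratio was 0.0565 (95% interval -0.00745 to 0.161, bootstrap). With each 3′ end change lowered by 2 SE, since those peaks were chosen by their calls, it was 0.0813 (-0.0117 to 0.236). As a median over genes, this argues against a change of equal size along the whole gene. With 62.5% of promoters in the same direction (43.7% to 78.9%, exact binomial), a far smaller change at promoters stays open. Single genes can differ from the median, and 5 of the 32 had a called promoter peak. At Scd1 and Cyp4a14 called promoter peaks changed by 1.78 and -1.70, against 3.33 and -3.43 at the 3′ end.

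Changed peaks lay at promoters less often than other peaks. Higher and lower calls were pooled here, 50 of 910 at a promoter. Taken apart and with 1 library left out, the deficit did not pass in 5 fits for lower peaks and in 1 for higher peaks. For lower peaks it was also absent with a 5 kb window. Within deciles of mean signal the pooled odds ratio was 0.365 (0.265 to 0.494). With the promoter share of reads as a covariate it was 0.391 (0.297 to 0.506), so neither signal level nor that share accounts for the pooled deficit. The spread between replicates at promoters was 0.919 times that of other peaks of the same signal (0.787 to 1.00 over deciles), so a larger spread does not account for it either. The absolute log2 change at promoters was 0.752 times that of other peaks. Accessibility that differs less at promoters than elsewhere between these feeding states may explain this, as a hypothesis found and tested on the same data.

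Of 100 genes with at least 2 called peaks, 91 had 1 direction, against 47.8% expected from the split of all calls and the number of called peaks of each gene. The 9 others were Ahcy, Asap1, Epb41l4b, Fabp1, Gadd45b, Gpx5, Pim3, Ppp1r3b and Tshz2. The median change over all other peaks of these genes, called or not, was 0.189 of that at the called peak with the smallest p (95% interval 0.161 to 0.231, bootstrap), which argues against a shift of the whole locus by 1 amount; choosing that peak by its p lowers the ratio and choosing genes with 2 called peaks raises it, and this test replaced one that split peaks by their calls. In 79 genes whose outermost called peaks lie over 2 kb apart, these had 1 direction in 88.6% (79.5% to 94.7%), against 54.7% expected for a pair, so reads shared by neighbouring peaks do not account for it. No biological explanation was tested.

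Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many called peaks; it gave 910 and the highest other 1. For lists the real split gave 8 and the highest other 4, again with 1 split as large as the real one. The other splits gave 0, 4, 4, 2, 1, 3, 3, 1 and 1 lists, though they called 0 or 1 peaks. Camera at its preset correlation of 0.01 thus also called lists for groupings that mix the feeding states. Among the called lists the estimated correlation ran from -0.0826 (lymphocyte markers) to 0.135 (lipogenesis). Where it is above the preset value, the camera p may be too small. With 10 splits a share under 0.05 cannot be reached.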
